A study of Mus musculus with 2 samples.

How the data were processed

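RNA from flow-sorted LT-HSCs of C57BL/6 mice was sequenced on a BGISEQ-500 instrument, with 1 library from wild type littermates and 1 from CCP3-deficient mice, per the labels. The labels do not say how many animals were pooled, of which sex, or which part of the gene was deleted. The deposited file of each library gave an Entrez gene identifier, RefSeq transcript identifiers, a length and an FPKM value per gene, per the file headers. FPKM values, fragments scaled for transcript length and library depth, were made by the authors. HISAT, HISAT2, RSEM and the mouse build mm9 are named in the submitters' processing notes, and their versions and settings are not given in the sources used here. Read counts were not used here. Symbols came from a RefSeq annotation of the mouse build GRCm38, in which 17169 of 17216 gene identifiers matched, and that annotation was used for names, neighbouring genes and transcript GC content. Because the builds differ, no coordinates are given.

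The smallest listed value was 0.01 FPKM, and a gene absent from a file was taken as 0 and is called not listed. Of the 17216 genes, 898 were listed only in the wild type library, with a median of 0.07 FPKM, and 684 only in the knockout-labelled library, with a median of 0.06 FPKM. FPKM sums were 577420 and 506124, so the values are not on the scale of a fixed sum. The depth was reconstructed from low values of short genes with 1 transcript, in which FPKM times length, less an offset of 41 and 39 bases, fell on multiples of 65 and 70.3. Of 552 and 537 such values, 87.3% and 89.0% lay within 0.15 of a whole read, where 30% would by chance for a step fixed in advance. Step and offset were chosen to bring these same values closest to whole reads, so 30% is too low as a chance figure. The steps gave depths of about 15.4 and 14.2 M reads. Reads per gene were estimated from them, and exact conditional 95% intervals of the knockout to wild type ratio were computed from the rounded estimates. These intervals are approximate, since they rest on estimated reads, and cover counting error only.

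The difference of a gene was log2(FPKM + 1) in the knockout-labelled library minus that in the wild type library, which understates the change of low genes. With 1 library per genotype there was no test, and genes were counted by a rule of size: a mean of at least 1 FPKM and a difference of at least 2-fold. Ratios quoted for single genes are of FPKM values without the pseudocount. The named genes were Agbl3, the 12 largest positive and 12 largest negative differences among genes with a mean of at least 5 FPKM (leaving out predicted genes, clone names, microRNA and small nucleolar RNA genes, pseudogenes and antigen receptor segments), every sex-linked gene measured, the 5 most abundant genes, and up to 4 members of each described list with a mean of at least 5 FPKM, taken by absolute difference, or by abundance where the list is described as similar. Genes named outside that rule are said to have been chosen after their values were seen, or are the remaining members of a small count or the lists' shared members. Some genes that the rule names are not reported here.

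In all, 41 gene lists were fixed before the data were examined, for stem cell identity, cell cycle, signalling, stress, metabolism, chromatin, tubulin modification, sex-linked genes, genes next to Agbl3 and markers of other blood, endothelial and stromal cells. For each list the median difference over members with a mean of at least 1 FPKM was given a percentile among 10000 random lists of the same size matched on expression in 20 bins, and a 95% bootstrap interval over members from 2000 draws. Lists with fewer than 5 measured members had no percentile. To describe length and GC content, the median difference of the 200 genes nearest in transcript length or GC content was subtracted from each gene. Alternatives covered the pseudocount, the filter on low values, the scaling, the matching of random lists, the mean in place of the median, estimated reads with TMM factors, and the length and GC centring.

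The procedure was tested on simulated data for 15634 genes. The simulated steps of 64 and 72 were recovered. Intervals built from the true steps covered 95.6% of true ratios, among unchanged genes that passed a minimum of reads in both simulated libraries. Coverage with reconstructed steps, or for genes with few reads such as Agbl3, was not tested. Changes of 4-fold and 0.25-fold were recovered in 100% of genes, while 2-fold changes, which sit at the threshold of 2-fold, were recovered in 26% of genes and 0.5-fold changes in 24%. Of unchanged simulated genes, 34 passed the rule of size, and 2.5% of unshifted lists lay outside the central 95%. Those lists were few and held genes drawn at random with independent counting error. That share therefore does not cover lists whose members vary together. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.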

Results

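RNA was sequenced from cells sorted as long-term haematopoietic stem cells (LT-HSCs), the rare bone marrow cells that sustain blood formation, from C57BL/6 mice lacking cytosolic carboxypeptidase CCP3 and from wild type littermates. The gate took cells without lineage markers that carried Sca-1, c-Kit and CD150 and lacked CD48. Cd48 RNA was nevertheless listed at 136 FPKM in the wild type library and 114 FPKM in the knockout library, so the identity of the cells is in doubt. There was 1 library per genotype, so no difference described here has a replicate check, no test between genotypes was possible, and every value compares these 2 libraries rather than the genotypes. The wild type library listed 16532 genes and the knockout library 16318, with 15634 in both. The step between low FPKM values implied about 15.4 M reads in the wild type library and 14.2 M in the knockout library. Reads per gene estimated from that step gave an approximate 95% interval for each ratio of FPKM values, which covers counting error only.

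The comparison asked which genes differ in cells sorted as LT-HSCs from mice that lack CCP3. This enzyme trims glutamate residues from proteins and is encoded by Agbl3 (Entrez gene 76223). Agbl3 was listed at 1.11 FPKM in the wild type library and 0.66 FPKM in the knockout library, from about 23 and 15 reads. The knockout to wild type ratio was 0.595 (95% counting interval 0.289 to 1.19), so the counted transcript was not lost and a partial reduction was not detectable at this depth. The labels do not say which part of the gene was deleted, and transcripts outside that part would still be counted, so Agbl3 did not check the genotype label. The library is therefore called the knockout-labelled library throughout, and each direction rests on that label. Among the other cytosolic carboxypeptidases, Agbl5 was listed at 52.0 FPKM in the wild type and 38.4 FPKM in the knockout-labelled library, and Agtpbp1 at 10.3 and 12.9 FPKM. All 6 measured genes of the TTLL family, members of which add glutamate, glycine or tyrosine residues to tubulin, were within 1.5-fold. So were all 10 tubulin genes, among them Tuba1b (818 and 766 FPKM) and Tubb5 (427 and 425 FPKM).

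Neutrophil marker, unfolded protein response and Xist transcripts were higher in the knockout-labelled library, while interferon-stimulated, B cell, dendritic cell, ribosomal protein, globin and Y-linked transcripts were lower. Of 11985 genes with a mean of at least 1 FPKM, 145 were at least 2-fold higher and 186 at least 2-fold lower on the log2(FPKM + 1) scale, and 10518 (87.8%) lay within 1.5-fold. Transcripts under 300 bases made up 42 of the higher and 59 of the lower genes. Not listed in the wild type library were 30 of the higher genes, and 40 of the lower were not listed in the knockout-labelled library. The counting interval excluded a ratio of 1 for 106 of the higher and 134 of the lower genes. In 20 simulated library pairs that differed by counting error alone, at most 42 genes were higher and at most 42 lower. When both libraries were scaled to the same sum, the median over all genes moved to 0.18 and the split became 359 higher and 226 lower, so that the share of higher genes went from 43.8% to 61.4%.

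The largest positive differences with a clear gene assignment included Slpi, a secreted inhibitor of neutrophil elastase, at 46.3 FPKM in the wild type and 237 FPKM in the knockout-labelled library, a ratio of 5.11 (4.68 to 5.59). Clu followed with a ratio of 3.68 (2.99 to 4.55), then Prom1 with 3.26, B4galt6 with 2.95, Gda with 2.89, the extracellular matrix gene Fn1 with 2.86, the coagulation factor gene F10 with 2.78 and glutathione reductase, Gsr, with 2.69. The globin genes were lower, with Hba-a1 at 764 FPKM in the wild type and 155 FPKM in the knockout-labelled library and Hbb-bs at 457 and 107 FPKM. The interferon regulatory factor gene Irf7 was listed at 26.2 FPKM in the wild type and 8.55 FPKM in the knockout-labelled library, Cox6a2 at 9.58 and 2.41 FPKM, and Pet117 at 9.61 and 1.05 FPKM from about 42 and 4 reads. Several of the largest differences fell in near-identical gene copies between which reads could be split and are uncertain as single genes. Hmga1b was not listed in the wild type library and stood at 16.5 FPKM in the knockout-labelled library, yet the sum of Hmga1 and Hmga1b had a knockout to wild type ratio of 1.11. The histone genes H2ac10 and H2ac7 were lower and H2ac24 higher, while the sum over 15 H2ac genes was 1.23-fold higher in the wild type library. Tmem254c was 20.3-fold higher in the wild type library, against 2.71-fold for the sum of its 3 copies, and the 7SL RNA genes Rn7s1 and Rn7s2 held the same value in each library. The alpha globin sum was 4.76-fold and the beta globin sum 3.97-fold higher in the wild type library.

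Sex-linked transcripts differed between the libraries, and both libraries listed Xist together with Y-linked genes. Xist, the RNA of the inactive X chromosome, was listed at 5.38 FPKM in the wild type and 44.2 FPKM in the knockout-labelled library, a ratio of 8.21 (7.78 to 8.68). Its antisense partner Tsix stood at 3.37 and 17.4 FPKM, but the sources used here do not say whether counting used strand, so reads of this pair cannot be separated. All 4 Y-linked genes measured were lower in the knockout-labelled library, with Eif2s3y at 44.6 and 11.5 FPKM, Kdm5d at 6.66 and 2.10 FPKM, Ddx3y at 13.8 and 5.93 FPKM, and Uty at 3.73 and 1.89 FPKM. The median over the 6 sex-linked genes was −0.90 (percentile 0 of matched random lists), but its members went both ways and their mean was −0.01.

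Neutrophil and monocyte markers were higher and B cell and dendritic cell markers lower in the knockout-labelled library. The medians of mast cell, basophil and eosinophil markers and of natural killer markers lay inside the central 95% of random lists, though some alternative settings placed each list outside. Among 29 neutrophil markers, 18 were at least 1.5-fold higher and 0 at least 1.5-fold lower, with a median difference of 0.67 (95% bootstrap interval over members 0.42 to 0.77; percentile 100 of random lists matched on expression). The neutrophil collagenase gene Mmp8 was listed at 7.84 FPKM in the wild type and 21.7 FPKM in the knockout-labelled library, Chil3 at 67.0 and 157 FPKM, Ifitm6 at 25.1 and 52.7 FPKM, and the granule protease gene Ctsg at 895 and 1832 FPKM. Among 28 monocyte and macrophage markers, 5 were at least 1.5-fold higher and 0 lower, with a median of 0.28 (0.02 to 0.50), which was 0.15 with a pseudocount of 5 and 0.48 with equal sums. These 5 were Fn1, Ccr2 (13.5 and 29.2 FPKM), F13a1 (40.6 and 81.2 FPKM), Lyz1 (5.16 and 8.55 FPKM) and Cd14 (1.27 and 2.53 FPKM). Among 23 B cell markers, 14 were at least 1.5-fold lower, with a median of −0.64 (−0.99 to −0.49; percentile 0), which was −1.12 over members with a mean of at least 5 FPKM and −0.28 with a pseudocount of 5. Among B cell markers with a mean of at least 5 FPKM, the surrogate light chain genes Igll1 (11.7 and 3.46 FPKM) and Vpreb1 (7.79 and 2.45 FPKM) differed most. The early lymphoid marker Ly6d (19.3 and 7.28 FPKM) and the adaptor gene Blnk (15.5 and 5.98 FPKM) followed. The only B cell list member at least 1.5-fold higher was Jchain (84.6 and 172 FPKM), singled out after its value was seen. Among 21 dendritic cell markers, 15 were at least 1.5-fold lower and 0 higher, with a median of −0.77 (−0.96 to −0.59), and the class II genes H2-Aa (44.8 and 18.5 FPKM) and H2-DMa (39.0 and 19.1 FPKM) were among them. Among 20 T cell markers, 7 were at least 1.5-fold lower, with a median of −0.26 at percentile 0.46, and examples were Il7r (10.2 and 4.66 FPKM) and Cd8b1 (7.54 and 3.66 FPKM). The T cell median returned inside the central 95% after centring on genes of similar transcript length (−0.19, percentile 3.25), and also with TMM scaling, with no filter on low values and with a pseudocount of 5; it was −0.57 (percentile 0) at a mean of at least 5 FPKM and −0.11 (percentile 0.58) with equal sums.

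**Figure D1:**
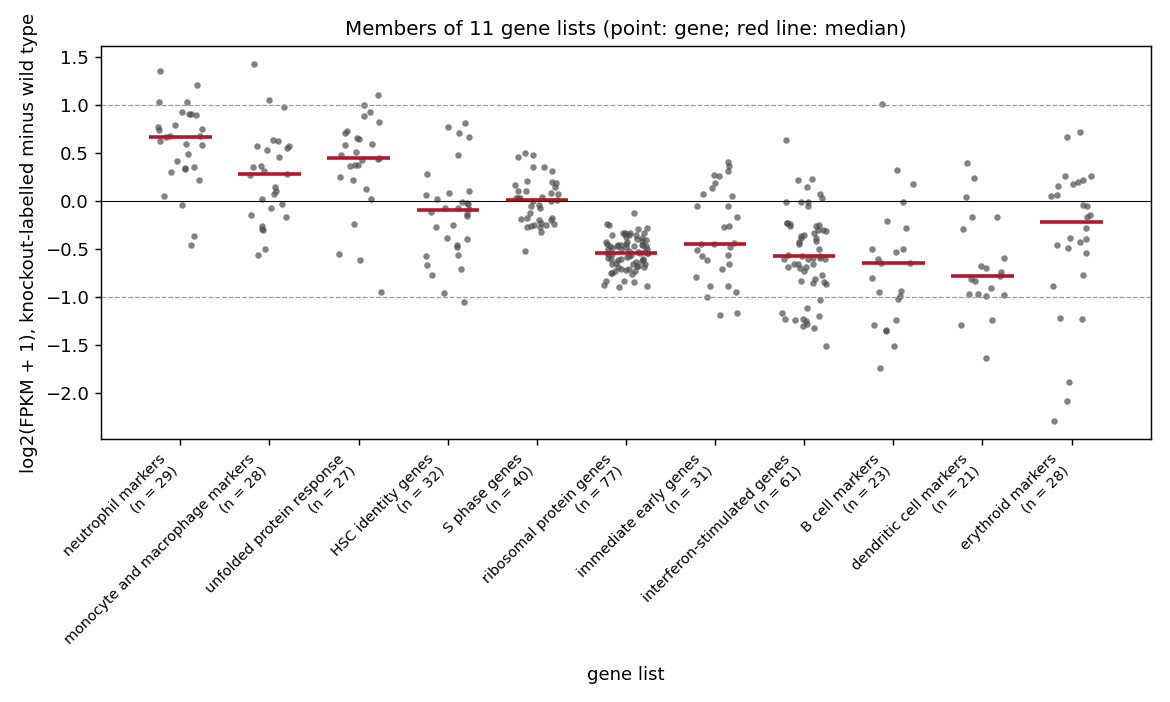
Difference of log2(FPKM + 1), knockout-labelled minus wild type library, for the measured members of 11 gene lists, with 1 point per gene, a red line at the list median and dashed lines at 1 and −1. Most of the 29 neutrophil markers lay above 0 and all 77 ribosomal protein genes below 0, while the 40 S phase genes lay around 0; the medians of HSC identity genes (negative) and S phase genes (near 0) changed sign under at least 1 other scaling.

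Interferon-stimulated genes and immediate early genes were lower in the knockout-labelled library, beside the differences in neutrophil, B cell and dendritic cell markers. Of 61 interferon-stimulated genes, 30 were at least 1.5-fold lower, with a median of −0.57 (−0.66 to −0.38; percentile 0), or −0.37 with a pseudocount of 5. After Irf7, the largest differences were in the GTPase genes Tgtp1 (27.5 and 10.4 FPKM) and Tgtp2 (48.2 and 19.2 FPKM), which are close copies, and in Xaf1 (14.5 and 5.28 FPKM). The only member at least 1.5-fold higher was Ifi205 (3.68 and 6.30 FPKM), singled out after its value was seen. Of 31 immediate early genes, 10 were at least 1.5-fold lower and 0 higher, with a median of −0.44 (−0.57 to −0.05; percentile 0), or −0.29 with equal sums. The transcription factor genes Nr4a1 (87.3 and 37.9 FPKM) and Egr1 (186 and 83.0 FPKM) led this list, followed by the mRNA decay factor gene Zfp36 (207 and 103 FPKM) and Ier2 (148 and 76.2 FPKM).

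Ribosomal protein transcripts were lower and unfolded protein response transcripts higher in the knockout-labelled library, beside the differences in neutrophil, B cell and dendritic cell markers. All 77 ribosomal protein genes were lower, 30 of them by at least 1.5-fold, with a median of −0.53 (−0.58 to −0.47; percentile 0), or −0.34 with equal sums, and their share of the FPKM sum was 31.3% in the wild type and 24.3% in the knockout-labelled library. Rpl14 (2177 and 1174 FPKM), Rpl38 (1788 and 976 FPKM) and Rps27 (3767 and 2099 FPKM) were among those that differed most. The 5 most abundant genes of the series were Rpl23a (9732 and 6094 FPKM), the translation elongation factor gene Eef1a1 (8060.2 and 6635 FPKM), Rps23, Rps24 and Rpl35. Of 76 nuclear genes of oxidative phosphorylation, 4 were at least 1.5-fold lower, namely Cox8a (84.2 and 49.0 FPKM), Atp5g2, Ndufs8 and Cox4i1, with a median of −0.21 (percentile 0.1), or −0.03 (percentile 0.03) with equal sums. Of 27 unfolded protein response genes, 11 were at least 1.5-fold higher, with a median of 0.45 (0.37 to 0.65; percentile 100). Among members with a mean of at least 5 FPKM, the chaperone genes Sdf2l1 (39.1 and 85.5 FPKM) and Hyou1 (45.3 and 91.9 FPKM) differed most. The degradation factor gene Edem1 (8.06 and 16.2 FPKM) and the chaperone gene Pdia4 (51.1 and 95.2 FPKM) followed. In all, 4 members were below 0, so the list did not move as a whole. They were Trib3 (2.40 and 0.77 FPKM) and Ppp1r15a (115 and 75.1 FPKM), both at least 1.5-fold lower, with Ddit3 (34.8 and 23.5 FPKM) and Atf4 (184 and 156 FPKM). These 4 were singled out after their values were seen. Heat shock genes had a median of 0.14 (percentile 98.2), with Hspa1a at 14.6 and 29.3 FPKM and Hspa1b at 26.1 and 42.5 FPKM. These are near-identical copies, and the list returned inside the central 95% with TMM scaling.

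Across 8817 genes with a mean of at least 5 FPKM, the difference followed transcript length, with a Spearman correlation across genes of 0.50, and genes are not independent replicates. The median difference was −0.30 for transcripts under 1000 bases and 0.28 for those over 5000 bases. After centring each gene on genes of similar length outside its list, the ribosomal protein median was −0.29 (percentile 0), the oxidative phosphorylation median 0.07 (percentile 88.3) and the unfolded protein response median 0.40 (percentile 100).

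**Figure D2:**
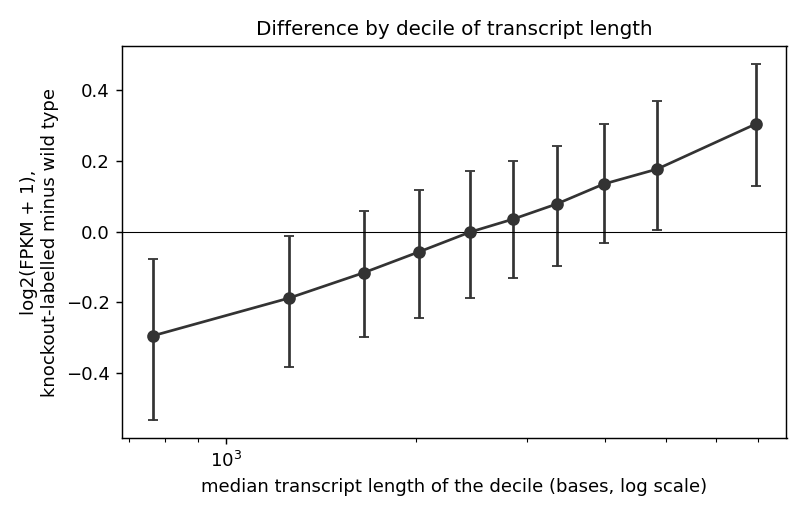
Median difference of log2(FPKM + 1), knockout-labelled minus wild type library, in 10 equal groups of genes by transcript length (log axis, bases), with bars for the interquartile range of genes. The medians ran from −0.29 in the shortest group to 0.30 in the longest.

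Stem cell genes went both ways and cell cycle genes were similar in the 2 libraries. Of 32 HSC identity genes, 5 were at least 1.5-fold lower and 4 higher, with a median of −0.09 at percentile 9.77. That median became 0.08 (percentile 11.3) when sums were scaled to be equal and −0.21 (percentile 0.23) after centring on transcript length. Over HSC identity genes with a mean of at least 5 FPKM it was −0.32 (percentile 0.01), outside the central 95%. Procr (29.0 and 14.5 FPKM), Ly6a, which encodes Sca-1 (49.1 and 28.4 FPKM), Robo4 and Ifitm1 were among the lower genes, and Itga6, Sult1a1 and Vwf among the higher. Sult1a1 and Vwf were named after their values were seen. The 30 HSC transcription factor genes had a median of 0.05 and a mean of −0.01, with Fli1 at 20.7 and 37.6 FPKM against Nr4a1 and Egr1, which were lower. Among 16 multipotent progenitor genes the lymphoid gene Dntt was listed at 341 and 149 FPKM while Ctsg was higher, and the median was −0.13 (percentile 20.1), outside the central 95% after length centring (percentile 0.76) and with TMM scaling (percentile 0.59). All 40 S phase genes and all 46 G2/M genes were within 1.5-fold, with medians of 0.01 and 0.07. With equal sums, where the median of all genes moved to 0.18, they were 0.20 and 0.26. The S phase median changed sign under upper-quartile scaling (−0.02). Pcna was listed at 375 and 311 FPKM, Mcm6 at 164 and 150.5 FPKM, Top2a at 163 and 191 FPKM and Mki67 at 98.9 and 140.3 FPKM. Genes of the sort gate were examined after the values were seen. Cd48, whose protein the gate excluded, was listed at 136 and 114 FPKM, and Slamf1, which encodes CD150, at 2.14 and 3.40 FPKM, with Kit at 59.7 and 56.5 FPKM, and Cd34 at 248 and 177 FPKM. Flt3, a gene of multipotent progenitors, was listed at 155 and 82.5 FPKM. The neutrophil precursor gene Mpo was listed at 1842 and 2792.5 FPKM in the same libraries. The Cd48 to Slamf1 ratio was 63.7 in the wild type and 33.5 in the knockout-labelled library. RNA levels do not give surface protein, but these values leave it in doubt whether the sorted cells were LT-HSCs, alone or in the main. All values describe the cells as sorted.

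**Figure D3:**
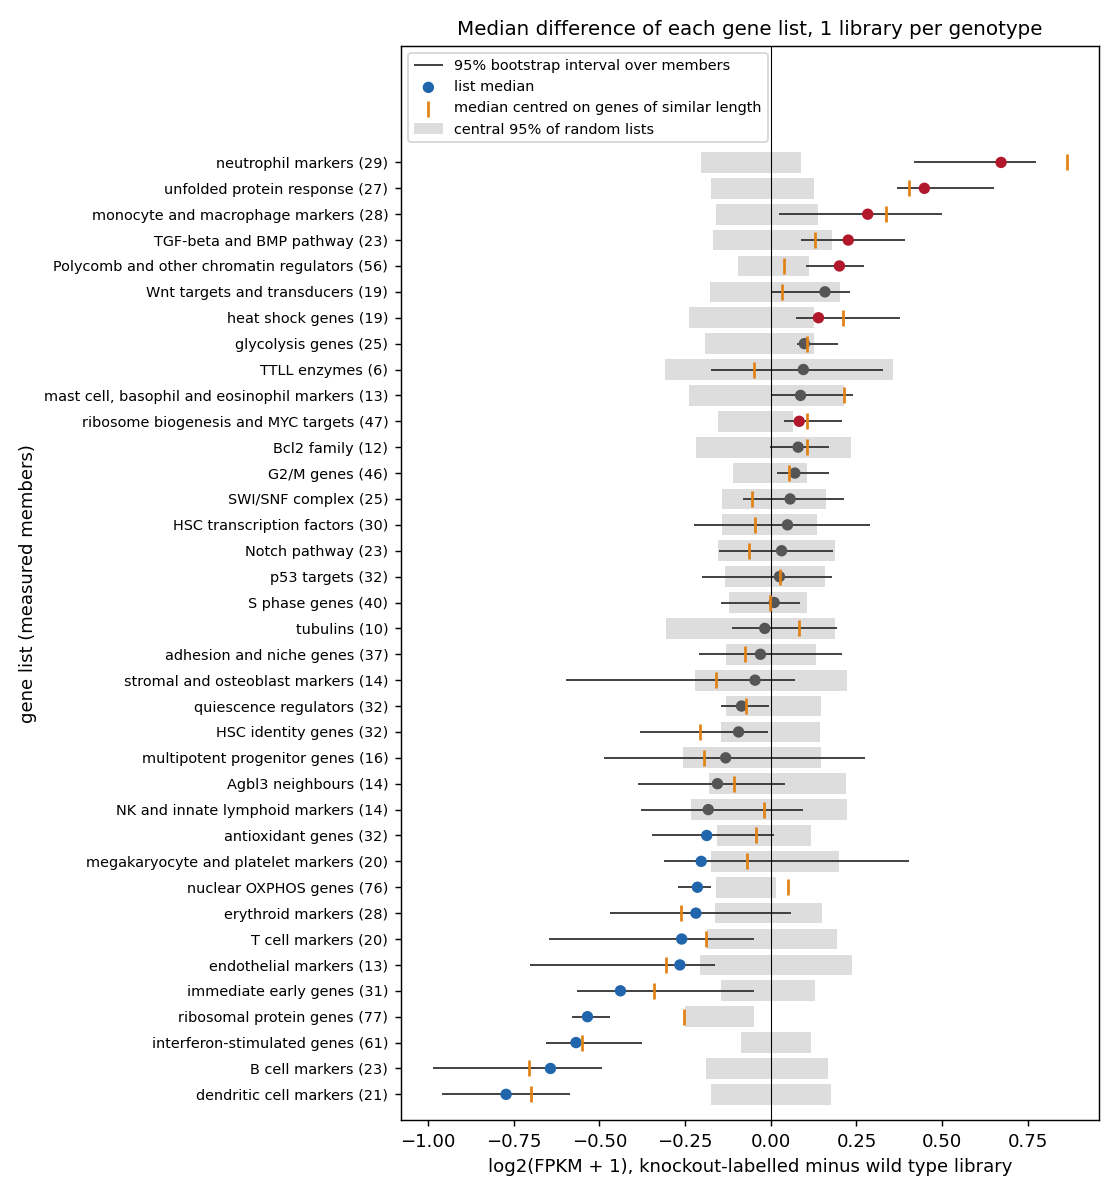
Median difference of log2(FPKM + 1), knockout-labelled minus wild type library, for 37 gene lists (the sex-linked list, with a median of −0.90, is left out), with red or blue points for medians outside and dark grey points for medians inside the central 95% of random lists matched on expression (grey bars), 95% bootstrap intervals over members (lines) and length-centred medians (orange ticks, to which the grey bars do not apply). Of the lists drawn, neutrophil markers were highest (0.67) and dendritic cell markers lowest (−0.77). Medians of the HSC identity, quiescence, adhesion, tubulin and stromal lists and of the Agbl3 neighbours turned positive when sums were scaled to be equal. That scaling moved the median of all genes with a mean of at least 1 FPKM to 0.18, and these lists stayed inside the central 95%. The S phase median turned negative under upper-quartile or TMM scaling.

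Of 38 gene lists with at least 5 measured members, 19 had a median outside the central 95% of matched random lists. Of these 19, 7 lay above and 12 below. About 1.9 would lie outside if list members varied independently, as genes drawn at random were taken to do. Members of a list can vary together, so 1.9 is not a chance expectation for these lists. Whether 19 exceeds chance was not tested. The lists share members and percentiles describe these 2 libraries only. After length centring, 13 of the 19 stayed outside, or 14 where the neighbours were taken from outside the list.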

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

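The measures compared between the libraries and their alternatives were fixed before the data were examined, except estimated reads with TMM factors, the requirement that the counting interval exclude 1, the removal of transcripts under 300 bases, and the length and GC centring, which were chosen after seeing the data, as were the tests of sort purity, mature neutrophils, granulocyte-committed progenitors and the mix of sexes. The counts of genes at least 2-fold higher and lower (145 and 186) depended on the pseudocount and the filter. They were 272 and 317 with a pseudocount of 0.1, 31 and 44 with a pseudocount of 5, and 70 and 88 for genes with a mean of at least 5 FPKM, where fewer genes were counted. Scaling both libraries to the same sum gave 359 higher genes, where the median of all genes with a mean of at least 1 FPKM moved to 0.18 and every value grew against the pseudocount, while the 226 lower genes stayed within 1.5 times. The other settings gave 103 to 186 higher and 127 to 233 lower genes. The Agbl3 difference was negative under every scaling and pseudocount tried, from −0.67 to −0.11. A pseudocount cannot change that sign, so this adds little to the counting interval, which includes a ratio of 1. The number of lists outside the central 95% ranged from 16 to 20. The mean over members of the megakaryocyte and platelet list was 0.0003, against a median of −0.20, because its members went both ways. The oxidative phosphorylation median became 0.0491 after length centring, or 0.0688 with neighbours from outside the list, so its call did not hold apart from the length trend. Beside these 2 lists, the calls for Polycomb and other chromatin regulators, antioxidant genes, T cell markers and ribosome biogenesis genes ended with length centring, giving 13 of 19 kept; with neighbours from outside the list the ribosome biogenesis call was kept (percentile 98.1). The TGF-beta and antioxidant calls ended at a mean of at least 5 FPKM, where the sex-linked list had too few members for a percentile. The heat shock and ribosome biogenesis calls ended with TMM factors and with unmatched random lists, the T cell call with TMM factors, no filter or a pseudocount of 5, the megakaryocyte call with a pseudocount of 5, and the antioxidant and sex-linked calls by the mean. Lists inside the central 95% moved outside it under some settings: HSC identity genes (percentile 0.01 at a mean of at least 5 FPKM and 0.23 with length centring), natural killer markers (1.43 at that mean, 0.59 with no filter and 2.09 with equal sums), multipotent progenitor genes, Agbl3 neighbours (0.67 with TMM factors), glycolysis genes (98.8 by the mean and 99.2 with GC centring) and mast cell, basophil and eosinophil markers. Medians that moved by over 1.5 times and stayed outside the central 95% included, with equal sums, heat shock (0.33), Polycomb (0.39), TGF-beta (0.39) and monocyte genes (0.48), with a pseudocount of 5 erythroid (−0.11), monocyte (0.15) and B cell markers (−0.28), and B cell markers at a mean of at least 5 FPKM (−1.12). The planned use of deposited counts with TMM factors was not run, as no counts were used here. No paired analysis was possible because each genotype has 1 library. Depth limits low genes such as Agbl3, whose counting interval spans a ratio of 0.289 to 1.19.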

Other observations

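The globin genes and 5 endothelial markers were lower in the knockout-labelled library, while other erythroid markers and platelet genes went both ways. Of 28 erythroid markers, 7 were at least 1.5-fold lower, 2 at least 1.5-fold higher and 19 within 1.5-fold. Their median was −0.22 (percentile 0.44), or −0.10 with equal sums, and its bootstrap interval over members included 0 (−0.47 to 0.06); the heme synthesis gene Alas2 (9.48 and 3.47 FPKM in the wild type and knockout-labelled library) followed the globins, while Tfrc (20.6 and 34.7 FPKM) and Rhag were higher. Of 13 endothelial markers, 5 were at least 1.5-fold lower, with a median of −0.27 (percentile 0.785), which was −0.16 with no filter on low values, −0.10 with equal sums and −0.57 at a mean of at least 5 FPKM: Egfl7 (98.8 and 48.0 FPKM), Fabp4 (9.54 and 4.27 FPKM), Emcn (15.1 and 7.40 FPKM), Robo4 and Tie1. The single higher member was Vwf (2.47 and 4.53 FPKM), chosen after its value was seen. Of the 29 endothelial list genes, 7 also stood in other lists, and Robo4 and Vwf were HSC identity genes too. Among 20 megakaryocyte and platelet markers, with a median of −0.20 (percentile 1.26), Gp9 was lower, and F10 and Selp (15.6 and 33.0 FPKM) higher. That median came inside the central 95% with length centring (−0.07, percentile 26.8), with a pseudocount of 5 (percentile 3) and by the mean over members (percentile 47.7), and was −0.05 with equal sums. Stromal markers had a median of −0.05, which became 0.11 (percentile 37.5) when sums were scaled to be equal. Of 14 measured members 4 were at least 1.5-fold lower and 2 higher. The niche chemokine gene Cxcl12 was listed at 11.4 and 4.57 FPKM, while the 2 higher members were Fn1 (10.8 and 30.8 FPKM) and Mgp (1.81 and 3.29 FPKM). Natural killer markers had a median of −0.18 (percentile 6.13), and mast cell, basophil and eosinophil markers a median of 0.09 (percentile 81.3), which moved outside the central 95% after length centring (0.21, percentile 99.1).

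Among chromatin, signalling and metabolic lists, Polycomb and other chromatin regulators had a median of 0.20 (percentile 99.99), with Tet2 (3.45 and 7.26 FPKM), Crebbp (7.97 and 14.6 FPKM) and Suz12 (24.5 and 41.4 FPKM) at least 1.5-fold higher, and a median of 0.04 (percentile 80.7) after length centring. TGF-beta and BMP genes had a median of 0.23 (percentile 99.3), which was 0.11 and inside the central 95% at a mean of at least 5 FPKM (percentile 83). It shrank but stayed outside after length centring (0.13, percentile 97.9), with no filter on low values (0.15) and with a pseudocount of 5 (0.15). Ribosome biogenesis and MYC targets had a median of 0.08 (percentile 98.7) and came inside with TMM factors, unmatched random lists or length centring (percentile 97.2), and the median was 0.27 (percentile 98.9) with equal sums. Antioxidant genes had a median of −0.19 (percentile 0.99), with Gsr (28.7 and 77.2 FPKM) going the other way. The median was −0.02 (percentile 0.79) with equal sums, and came inside with length centring (percentile 18.6), at a mean of at least 5 FPKM and by the mean over members. Medians lay inside the central 95% for Wnt (0.16), glycolysis (0.10), TTLL (0.09), Bcl2 family (0.08), SWI/SNF (0.06), Notch (0.03) and p53 target genes (0.03, with a mean of −0.02). The same held for tubulins (−0.02, with a mean of 0.03), adhesion and niche genes (−0.03), quiescence regulators (−0.09) and the genes next to Agbl3 (−0.16, percentile 3.98). The medians of these 4 turned positive when sums were scaled to be equal, where the median of all genes moved to 0.18, and stayed inside the central 95%. In the glycolysis list 4 of 25 members were at least 1.5-fold higher, among them the lactate transporter genes Slc16a1 (10.3 and 22.8 FPKM) and Slc16a3 (5.65 and 12.4 FPKM). The 3 members at least 1.5-fold lower were Ldhb (37.7 and 22.1 FPKM), Pdk2 and Aldoc, named after their values were seen, while Gapdh was listed at 3659 and 3368 FPKM. The carboxypeptidase and hedgehog lists had too few measured members for a percentile, with 2 and 4, and mitochondrial transcripts were not analysed here.

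The tests of sort purity, mature neutrophils, granulocyte-committed progenitors and the mix of sexes were chosen after the results they bear on were seen; those of length and GC content were written after the list medians but before the centred values were known.

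Ribosomal protein genes were lower and unfolded protein response genes higher in the knockout-labelled library, and transcript length and GC content were weighed as technical sources. Centring on genes of similar GC content outside each list left medians of −0.53 and 0.45, and centring on length left the unfolded protein response median at 0.40 (0.30 to 0.62), above its threshold of 0.22, so these trends are argued against as the main source. For ribosomal protein genes, length centring left −0.29 (bootstrap interval over members −0.34 to −0.24), at percentile 0 of random lists matched on expression. That interval measures spread among members, which can vary together, and not between libraries. The remainder of −0.29 argues against length as the whole source in these 2 libraries. The value passed the threshold of −0.27 set in advance, but that threshold lies inside the interval, a reading of the spread adopted after the value was seen, so whether length may account for most of the difference stays open. The cause of the remainder is open, and an effect of genotype is untested with 1 library each. Neutrophil, B cell and dendritic cell markers differed between the same libraries, and a link to them was not tested.

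Neutrophil markers were higher and B cell markers lower, although the gate removed lineage-positive cells; 5 of the 30 neutrophil and 3 of the 29 B cell list genes also stood in other lists, and stem and progenitor cells express some of them. Lower purity of the knockout-labelled sort that raised every other cell type alike would raise dendritic cell markers, but their median was −0.77 (−0.96 to −0.59). That median was known before it was brought in here. The list is not fully separate, as 4 of its 25 genes stood in other lists. These were Ly6d (B cell list), Flt3 and Irf8 (multipotent progenitor list) and Bst2 (interferon list). The main sorted cells may express such genes, and a fall there could hide added dendritic cells, so lower purity is not excluded. The medians of the neutrophil and B cell lists lay 1.31 apart (0.9995 to 1.71), which restates the pattern. Carry-over of a single lineage is not covered, nor is lower purity of the wild type sort. Carried-over mature neutrophils could be a source and stay open: the median of 5 early granule genes exceeded that of the 24 other neutrophil markers by 0.06 (−0.17 to 0.44), and a difference of 0.59 from 6 late genes picked after the values were seen rested on that choice. Camp was lower (207 and 152 FPKM) and S100a9 similar (2623 and 3069 FPKM), while Lcn2 (144 and 231 FPKM), Retnlg (56.8 and 97.7 FPKM) and Mmp9 (7.07 and 14.2 FPKM) were higher, as was the early gene Elane (535 and 861 FPKM). Apart from S100a9, these genes were named after their values were seen. More granulocyte-committed progenitors in the sort could be a source too, but the HSC identity median lay at percentile 9.8 of random lists, at 0.01 for members with a mean of at least 5 FPKM and at 0.23 after length centring, so the result depends on the setting and this cannot be told apart from a difference within the stem cells or an effect of genotype, which is untested.

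Xist was higher and Y-linked genes lower in the knockout-labelled library. A different mix of male and female animals in the 2 pools is a candidate source: all 4 Y-linked genes measured were lower where Xist was higher, and Xist and these genes were listed in both libraries. These values restate the pattern and are not a separate test of that source. Among the Y-linked genes the knockout to wild type ratio ran from 0.259 (counting interval 0.227 to 0.294) for Eif2s3y to 0.507 (0.412 to 0.621) for Uty. A changed share of male cells alone would lower these genes by a common factor, so it may not be the only source of these sizes. The labels do not give the sex of the animals, and with 1 library each the mix of sexes and the genotype differ together, so any sex-dependent transcript among the differences is confounded.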
